A study of Mus musculus with 14 samples.

How the data were processed

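RNA of the proximal epididymis of eight-week-old mice (100 ng labelled per array) was measured on 14 Clariom S mouse arrays, and each array was assigned to its genotype, surgery and replicate number by its labels. The deposited table used here held log2 values of 22206 probe sets in 2 parts, between 2.33 and 13.91, with 1 probe set in both parts at identical values. The submitters' processing notes name RMA, Affymetrix Expression Console and Partek 7.0 without giving their order or role. A comparison table by the authors gave a p-value and a ratio for each probe set. Its ratios equalled those of the log2 table within 0.001 on the log2 scale for 100.0% of them. The authors' p-values were used only for counts, after Benjamini-Hochberg adjustment. The 14 columns of array values in that table were not used, because their probe set identifier differed from that of the line in 5826 of 22207 lines (26.2%). A second deposited table of log2 values (28846 lines, up to 19.02), whose normalization is not given in the sources used here, served as an alternative. Deviations from the probe set mean correlated at 0.945 or more between the tables for the same array and at 0.606 or less for different arrays.

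Probe sets were named by the deposited symbols, with 20452 matched by RefSeq accession to current mouse symbols (915 updated) and 14 symbols that had turned into dates restored in the same way. The gene table used for names is of one mouse assembly, while the build of the arrays' annotation is not given in the sources used here, so no coordinates are printed. Of the 22206 probe sets 3 had no symbol, and 180 symbols had several. The probe set with the highest mean was kept for each symbol, which left 21929 genes. No filter on low values was applied and no detection calls were used. As a background, chosen after the data were seen, 1463 olfactory and vomeronasal receptor genes had a median of 3.69 and a 95th percentile of 5.31, and a fold against a group mean below that percentile is given as a lower bound computed from it. All arrays carried one scan date, so no batch could be compared, and arrays have no depth: their number limits the precision. For a gene with the median standard error, the 95% confidence interval reached 0.22 log2 to either side for EDL against sham in Ctl, 0.26 in cKO, 0.24 for each comparison of genotypes and 0.34 for the interaction.

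All comparisons came from a single limma model with a mean for each of the 4 groups and moderated standard errors (10 residual and 4.16 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes as the threshold. The 5 contrasts were EDL minus sham in Ctl and in cKO, cKO minus Ctl in sham and in EDL tissue, and the interaction. Errors are moderated standard errors and n gives the arrays of the groups compared. A total of 32 lists of cell type, pathway and response genes, fixed before the data were examined, were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists within each contrast, and again with an estimated correlation and with fry. Counts adjusted over the list alone used the same p-values. The named genes were the 10 largest rises and 10 largest falls past the threshold whose groups did not overlap or, where none passed, the 3 smallest p in each direction, with Arl13b, Krt5, Krt14, Trp63, Gli1, Ptch1 and up to 4 members of a list with the smallest p. Predicted genes were counted but not named, and not every gene the rule covers is reported here. Both the model and the lists were checked on simulated data with known changes: of 2-fold changes, 100% were recovered for EDL against sham in Ctl and 97.0% in cKO, with no wrong sign. The simulated noise was normal and independent between genes, so the shares recovered need not hold for the real arrays.

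The comparisons of surgeries took both sides of the same mice. The main model left the mouse out, since no statistical method of the authors states a block, and mouse (genotype and replicate number, a pairing that the labels do not state) entered as a fixed and as a random replicate block among the alternatives. The consensus correlation within mice was 0.109, and for 4 of 7 pairs the array of the same number was the best partner (correlations of deviations from -0.002 to 0.198). The other alternatives set before the data were examined were a second quantile normalization, centring on array medians, trended and robust variances, array weights, only the arrays compared, other thresholds, a filter on low values, other choices among probe sets, and leaving out each array and each mouse. The second table as a whole and the list tests with an array left out were added after the data were seen. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.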

Results

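Transcript levels were measured on single-colour Clariom S mouse arrays in the proximal epididymis of control mice (Ctl) and of mice with a conditional knockout of Arl13b in Krt5-positive basal cells (cKO). Arl13b encodes a small GTPase of the ciliary membrane, and basal cells lie at the base of the epididymal epithelium. One side of each mouse had its efferent ducts ligated (EDL), which cuts off the sperm and fluid that come from the testis, and the other side had a sham operation. Tissue was taken 48 h after surgery. There were 14 arrays from 7 mice: 4 Ctl sham, 4 Ctl EDL, 3 cKO sham and 3 cKO EDL arrays. The values were log2 intensities of 21929 named genes, with array medians between 6.96 and 7.06, and the number of arrays limits the precision. On the first principal component, which held 47.6% of the variance, the sham arrays lay between -36.5 and -13.8 and the EDL arrays between 16.8 and 27.1.

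Arl13b, the targeted gene, read 7.0, 7.06, 6.87 and 7.46 in the Ctl sham arrays and 7.24, 7.20 and 7.15 in the cKO sham arrays. It read 7.33, 7.36, 7.60 and 7.42 in the Ctl EDL arrays and 7.14, 7.58 and 7.16 in the cKO EDL arrays. The cKO minus Ctl difference was 0.10 ± 0.14 on the log2 scale in sham tissue (SE, n = 3 and 4, 95% interval -0.19 to 0.39, limma adjusted p = 0.999) and -0.13 ± 0.14 in EDL tissue (95% interval -0.42 to 0.16, adjusted p = 0.9). So no difference was detected at this number of arrays. The tissue holds many cell types besides basal cells, and the position of the probe set relative to the deleted part of the gene is not given in the sources used here. After EDL, Arl13b changed by 0.33 ± 0.13 in Ctl (adjusted p = 0.147) and 0.10 ± 0.15 in cKO (adjusted p = 0.77). Without Ctl sham replicate 5 the Ctl change was 0.45 with an adjusted p of 0.0301. Krt5, a keratin of basal cells, differed between genotypes by -0.20 ± 0.10 in sham and 0.25 ± 0.10 in EDL tissue (adjusted p = 0.999 and 0.766). Trp63, a transcription factor of basal cells, differed by 0.03 ± 0.11 and 0.01 ± 0.11 (adjusted p = 0.999 and 0.995). The hedgehog pathway genes Gli1 and Ptch1 differed by 0.18 ± 0.17 and -0.02 ± 0.11 in sham tissue and by 0.00 ± 0.17 and -0.13 ± 0.11 in EDL tissue, none past the threshold.

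**Figure D1:**
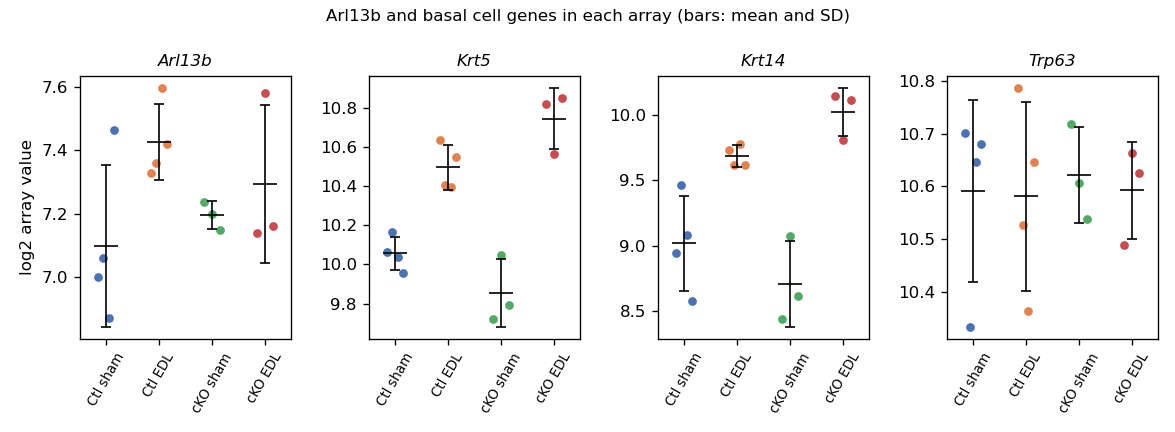
Log2 array values (vertical axis) of Arl13b and 3 basal cell genes in each array of the 4 groups, with the mean and SD of each group as bars. Arl13b lies between 7.15 and 7.24 in the cKO sham arrays, within the range of the Ctl sham arrays.

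The first question was how the proximal epididymis of Ctl mice responded to EDL (n = 4 and 4). The 10 largest falls included genes of the most proximal epithelium. Rnase10, a secreted ribonuclease-like protein that sperm need for normal transit, fell 42.7-fold (log2 change -5.42 ± 0.14). Etv5, a transcription factor induced by growth factor signalling, fell 24.4-fold (-4.61 ± 0.10), and the lipocalin Lcn9 fell 21.6-fold (-4.43 ± 0.12). Teddm2 fell 97.0-fold (-6.60 ± 0.09), and Pate10 fell to the level of olfactory and vomeronasal receptor genes, which served as background, so that its fall was at least 35.3-fold. The other large falls were Gcnt4, Defb48, Teddm1a, Elovl4 and Asb18, with log2 changes from -5.52 to -4.08. The largest rises, of which those reported here follow, were smaller. Sectm1b rose 4.82-fold (2.27 ± 0.23), Smarca1 3.28-fold and Pigr, which carries immunoglobulin A across epithelia, at least 1.71-fold over background (1.69 ± 0.25). Aif1 and Mrc1, both macrophage genes, rose by 1.55 ± 0.22 and 1.52 ± 0.34. Fgg, Saa3, Wfdc18 and Wfdc3 rose by 1.60, 1.55, 1.52 and 1.40. With mouse as a fixed replicate block Saa3 did not pass (adjusted p = 0.0585), but with mouse as a random block it did (0.0112). Fgg did not pass without Ctl sham replicate 3 or 5 or Ctl EDL replicate 3 or 4 (1.49 to 1.58, adjusted p from 0.0518 to 0.0672). In all, 727 genes rose and 1002 fell at a Benjamini-Hochberg adjusted p under 0.05 (limma), of which 54 and 231 changed at least 2-fold. With each array centred on its median, 567 rose and 1163 fell, which lowered the share of rises from 42.0% to 32.8%.

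Among the gene lists fixed beforehand, 11 of 15 initial segment principal cell genes fell and none rose in Ctl (adjusted over the list alone, 11 fell and 3 rose; camera adjusted p = 5.5e-19), Adam28 by -3.60 ± 0.13. Of 22 ERK pathway targets 17 fell and 5 did not pass (adjusted over the list alone, 17 fell and 1 rose; adjusted p = 2.43e-24), among them Etv1 (-2.63 ± 0.11) and the phosphatase gene Dusp5 (-1.95 ± 0.09). These 2 lists, which share Etv4, Etv5 and Dusp6, also passed with an estimated correlation (adjusted p = 0.00038 each), and no other list did. Of 18 sperm and spermatid genes 14 fell (adjusted over the list alone, 15; adjusted p = 3.29e-16, and 0.0558 with an estimated correlation), among them the sperm tail gene Akap4 (-2.31 ± 0.22) and Oaz3 (-2.05 ± 0.26). Of 17 cholesterol synthesis genes 13 fell (adjusted over the list alone, 16; adjusted p = 1.3e-17, and 0.0616 with an estimated correlation), among them Lss (-1.11 ± 0.09) and Cyp51 (-0.88 ± 0.11). The caput principal cell secretion list fell by its test (adjusted p = 0.00524, and 0.331 with an estimated correlation), with 5 genes lower, 1 higher and 6 not past the threshold, over all genes and adjusted over the list alone. Lcn8, Lcn10 and Cst11 fell by 1.05, 1.28 and 1.41. Its median change was -0.02 and its mean -0.36, and with an array left out the median was -0.06 to 0.02. In the ER stress list 3 of 12 genes fell, over all genes and adjusted over the list alone, among them Atf4 (-0.29 ± 0.07) and Herpud1 (-0.33 ± 0.08; list adjusted p = 0.00418, and 0.0558 with an estimated correlation). Atf4 did not pass without Ctl EDL replicate 5 (-0.24, adjusted p = 0.0532), nor Herpud1 without Ctl sham replicate 4 or Ctl EDL replicate 4 or 5 (adjusted p = 0.0592, 0.0546 and 0.0583).

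Macrophage and monocyte genes rose in Ctl after EDL: 12 of 17 passed over all genes and 17 adjusted over the list alone (adjusted p = 1.15e-15, and 0.0819 with an estimated correlation), among them the lysosomal marker Cd68 (0.94 ± 0.10) and the complement gene C1qc (1.02 ± 0.14). In the neutrophil list 2 of 13 rose (6 adjusted over the list alone), among them Cxcr2 (0.63 ± 0.15). The list's adjusted p was 0.00418, and 0.253 with an estimated correlation. In the acute phase and antimicrobial list 3 of 14 rose (6 adjusted over the list alone), Pigr, Saa3 and Lrg1 (1.08 ± 0.26; adjusted p = 0.00839, and 0.253 with an estimated correlation). In the cytokine and chemokine list 4 of 27 rose and 1 fell, over all genes and adjusted over the list alone; Csf1 and Il33 rose by 0.59 ± 0.12 and 0.90 ± 0.22 (adjusted p = 0.00811, and 0.331 with an estimated correlation). In the MHC class II presentation list 4 of 11 rose and 1 fell (5 and 2 adjusted over the list alone), with Cd74 up by 0.71 ± 0.14 (adjusted p = 0.0423, and 0.327 with an estimated correlation). The interferon-stimulated, fibroblast and matrix, endothelial and proliferation lists were higher by camera (adjusted p = 0.0137, 2.66e-05, 0.00425 and 0.00524, and 0.514, 0.348, 0.396 and 0.707 with an estimated correlation). In these lists 1 of 21, 2 of 17, 0 of 12 and 0 of 26 genes rose over all genes, and 1, 3, 5 and 0 adjusted over the list alone. Timp1, an inhibitor of matrix proteases, rose by 1.33 ± 0.36. Several of these calls lay near the threshold and were lost without 1 array. The changes where they were lost were 1.10 to 1.34 for Timp1, 0.73 to 0.88 for Il33 and 0.96 to 1.04 for Lrg1. The list medians were 0.20 to 0.29 for MHC class II (0.29 with all arrays), 0.14 to 0.16 for interferon-stimulated (0.24), 0.24 to 0.28 for proliferation (0.37) and 0.13 for cytokine genes (0.20). Without Ctl EDL replicate 3 the MHC class II and interferon-stimulated lists (adjusted p = 0.113 and 0.0832), Timp1, Il33 and Lrg1 (adjusted p = 0.0931, 0.0501 and 0.0512) did not pass. Without Ctl sham replicate 5 the interferon-stimulated, cytokine and proliferation lists (adjusted p = 0.127, 0.055 and 0.0728) and the same 3 genes (adjusted p = 0.11, 0.0663 and 0.0628) did not pass. Without Ctl EDL replicate 4 the proliferation list, Timp1 and Lrg1 did not pass (adjusted p = 0.114, 0.0892 and 0.0552), and without Ctl sham replicate 4 the MHC class II and proliferation lists (adjusted p = 0.0599 and 0.0515). Timp1 and Il33 did not pass without Ctl EDL replicate 5 (adjusted p = 0.075 and 0.063). Without Ctl sham replicate 2 the interferon-stimulated list, Timp1 and Il33 did not pass (adjusted p = 0.0686, 0.0925 and 0.0588), and without cKO EDL replicate 2 the MHC class II list (adjusted p = 0.054). Krt5 and Krt14 rose by 0.44 ± 0.09 and 0.67 ± 0.17 (adjusted p = 0.00956 and 0.023). Without Ctl sham replicate 2 or 5 or Ctl EDL replicate 2 or 4 Krt14 did not pass (0.52 to 0.65, adjusted p from 0.0512 to 0.0713). With mouse as a fixed replicate block Krt14 did not pass (adjusted p = 0.055), but with mouse as a random block it did (0.0166). The basal cell list did not pass by camera, without a block (adjusted p = 0.0769) or with mouse as a fixed replicate block (0.0791). It did not pass with an estimated correlation either (0.327), but passed by fry (0.0386). The T and NK cell and B cell lists did not pass (adjusted p = 0.875 and 0.715). The apoptosis and p53 response list, at an adjusted p of 0.0523, passed with mouse as a fixed replicate block in the list test (0.0252), but did not with an estimated correlation (0.271).

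**Figure D2:**
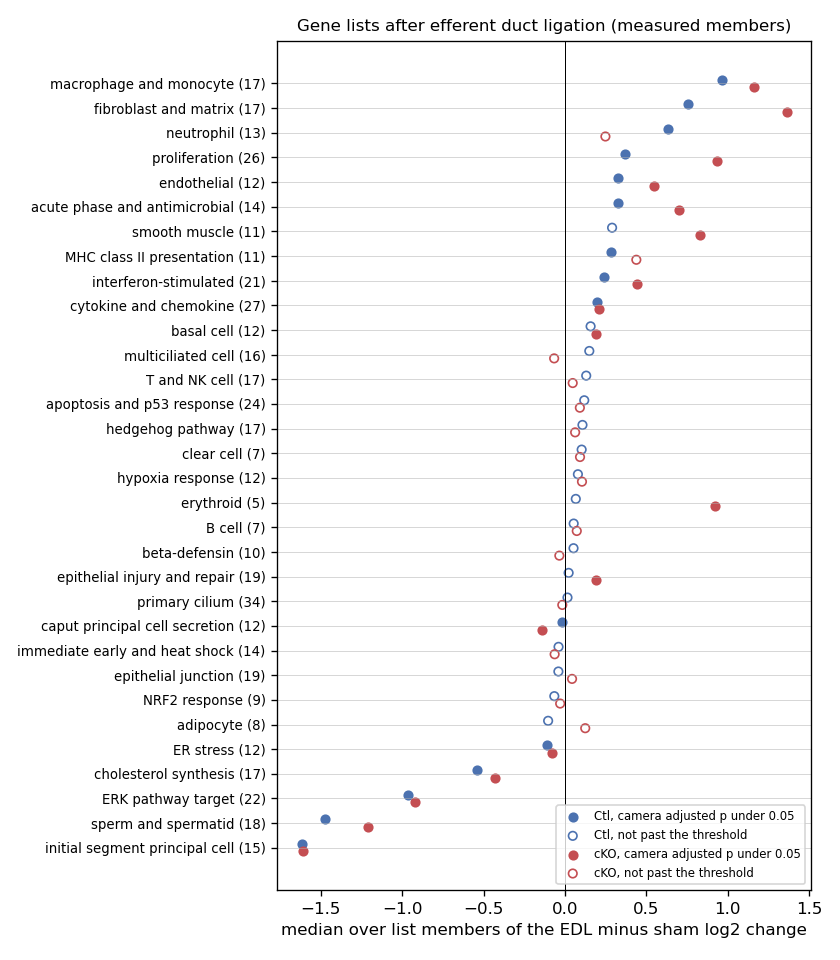
Median log2 change after EDL (horizontal axis) of each gene list in Ctl and cKO mice, with the number of measured genes in brackets and filled points for lists past a camera adjusted p of 0.05. The initial segment list fell by medians of -1.62 and -1.61, and the macrophage list rose by 0.96 and 1.16.

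The same question was asked in cKO mice (n = 3 and 3). Rnase10 fell 43.0-fold (-5.43 ± 0.17), Etv5 23.1-fold (-4.53 ± 0.11), Lcn9 18.3-fold (-4.19 ± 0.13) and Teddm2 119-fold (-6.90 ± 0.10), and Pate10 fell at least 42.5-fold. Defb48, Gcnt4, Teddm1a, Tecta and Elovl4 made up the other large falls, from -5.77 to -4.05. Of the 10 largest rises, Pate3, Cwh43, Defb38, Defb26 and Ly6f rose by 3.27 ± 0.96, 3.17 ± 0.80, 3.06 ± 0.81, 2.78 ± 0.63 and 2.10 ± 0.37, from low values in cKO sham tissue. All of these are among 17 genes, described below, that stood at least 2-fold lower in cKO than in Ctl sham tissue. Relative to Ctl sham tissue, the median of the 17 was -2.185, -1.582 and -1.976 in the cKO sham arrays. In the cKO EDL arrays it was -0.095, 0.337 and -0.284, so as a set they ended near the Ctl sham level. The remaining genes of the 10 largest rises, Ccl9, Ms4a6d, Ccr2, Lyz2 and the galectin gene Lgals1, rose by 2.26, 2.22, 2.19, 2.13 and 2.09. With mouse as a fixed replicate block Pate3 and Ccl9 did not pass (adjusted p = 0.0779 and 0.0703), but with mouse as a random block they did (0.034 and 0.0313). Without cKO sham replicate 2, of these 10 rises only Ly6f and Lyz2 passed; the other 8 did not, at 1.35 to 3.35 (adjusted p from 0.0666 to 0.191), among them Ccl9, Ccr2 and Lgals1 at 1.57, 1.35 and 1.37. Without cKO EDL replicate 2, 7 did not pass (adjusted p from 0.0566 to 0.126), and 4 did not without cKO EDL replicate 3, cKO EDL replicate 4 or cKO sham replicate 4 (adjusted p up to 0.126, 0.102 and 0.102). Pate3 did not pass without any 1 of the cKO arrays (2.89 to 3.62, adjusted p from 0.0699 to 0.126). Without an array of the Ctl groups Pate3, Ccl9 and Ccr2 did not pass in some cases (adjusted p up to 0.0578, 0.0554 and 0.0501). In all, 1106 genes rose and 1040 fell (limma, adjusted p under 0.05), of which 217 and 248 changed at least 2-fold. With each array centred on its median, 786 rose and 1467 fell, which lowered the share of rises from 51.5% to 34.9%. The count was 1063 without cKO sham replicate 2 and 1305 without cKO EDL replicate 2.

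**Figure D3:**
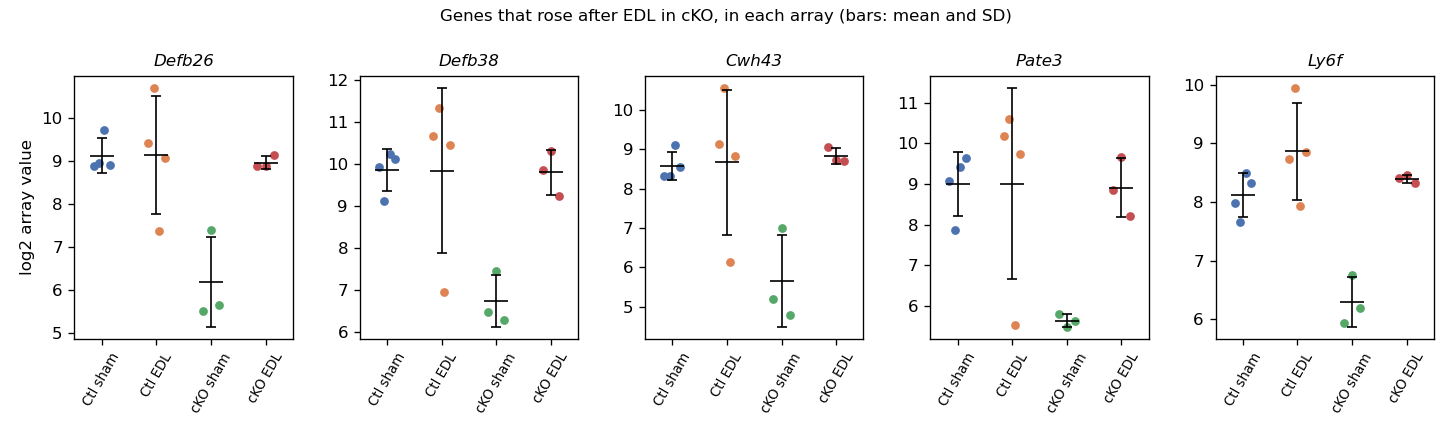
Log2 array values (vertical axis) of 5 of the largest rises after EDL in cKO mice, in each array of the 4 groups, with the mean and SD of each group as bars. Defb38 reads 6.94 in Ctl EDL replicate 4 and at least 10.45 in the other Ctl EDL arrays.

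The 6 lists that were lower by camera in Ctl were also lower by camera in cKO, though the caput secretion list had a median of -0.02 in Ctl. In the initial segment list 10 of 15 genes fell (12 adjusted over the list alone; adjusted p = 2.89e-20), and of the ERK pathway targets 17 fell and 1 rose, over all genes and adjusted over the list alone (adjusted p = 5.6e-21). With an estimated correlation these passed at adjusted p = 0.000563 and 0.000716, and no other list did. The sperm, cholesterol synthesis, caput secretion and ER stress lists had 9, 12, 5 and 3 genes lower (13, 15, 5 and 4 adjusted over the list alone), with camera adjusted p = 1.02e-09, 6.44e-12, 0.00013 and 0.00522, and 0.0989, 0.0989, 0.184 and 0.0972 with an estimated correlation. Akap4 fell by 1.84, Lss by 1.05, Lcn8 by 0.92 and Herpud1 by 0.53 on the log2 scale. Of the macrophage and monocyte genes 16 of 17 rose (17 adjusted over the list alone; adjusted p = 4.71e-16, and 0.0972 with an estimated correlation), Cd68 by 0.89 ± 0.11 and C1qc by 1.23 ± 0.16. Of the fibroblast and matrix genes 12 of 17 rose (15 adjusted over the list alone; adjusted p = 1.06e-09, and 0.186 with an estimated correlation), among them Timp1 (1.99 ± 0.41), the collagen crosslinking enzyme Lox (2.01 ± 0.43), Fn1 (1.94 ± 0.44) and Col5a1 (1.31 ± 0.29). Without cKO sham replicate 2 the median change of this list fell from 1.36 to 0.85, and the list passed (camera adjusted p = 1.01e-07). Without the same array Fn1 and Col5a1 did not pass (1.57 and 1.02, adjusted p = 0.0698 and 0.059), nor did Fn1 without cKO EDL replicate 2 (1.74, adjusted p = 0.0585). Of the endothelial genes 7 of 12 rose (8 adjusted over the list alone), Erg by 0.80 ± 0.17 and Cdh5 by 1.23 ± 0.27 (list adjusted p = 1.53e-06, and 0.184 with an estimated correlation).

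Basal cell genes rose in cKO after EDL: 5 of 12 passed (adjusted over the list alone, 5 rose and 1 fell; adjusted p = 0.00407, and 0.0989 with an estimated correlation), among them Krt5 (0.90 ± 0.11), Krt14 (1.31 ± 0.19) and the laminin receptor genes Itgb4 and Itga6 (0.71 ± 0.13 and 0.59 ± 0.12). The epithelial injury and repair list had 6 genes higher and 1 lower (9 and 2 adjusted over the list alone; adjusted p = 0.00483, and 0.0972 with an estimated correlation), with the matrix protease gene Mmp7 up by 1.34 ± 0.13 and the hyaluronan receptor gene Cd44 by 1.15 ± 0.19. The proliferation, acute phase, interferon-stimulated and cytokine lists had 3 of 26, 7 of 14, 4 of 21 and 2 of 27 genes higher (22, 7, 8 and 2 adjusted over the list alone). Their adjusted p values were 1.42e-09, 0.000575, 0.000575 and 0.0345, and 0.351, 0.0989, 0.351 and 0.417 with an estimated correlation. The cytokine list did not pass without cKO sham replicate 2 or cKO EDL replicate 2 (medians 0.19 and 0.11 against 0.21 with all arrays; adjusted p = 0.2 and 0.187). The replication gene Mcm7 rose by 0.91 ± 0.24, but did not pass with mouse as a fixed replicate block (adjusted p = 0.0581, and 0.0214 with mouse as a random block) or without any 1 of the cKO arrays except EDL replicate 3 (0.72 to 0.92, adjusted p from 0.0648 to 0.132), and Pigr rose by 1.54 ± 0.28. In the smooth muscle list 4 of 11 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.000933, and 0.351 with an estimated correlation), with Synpo2 up by 0.83 ± 0.23. Synpo2 did not pass without any 1 of the cKO arrays except sham replicate 4 (0.68 to 0.93, adjusted p from 0.0501 to 0.14). The erythroid list passed by camera (adjusted p = 0.0147, and 0.351 with an estimated correlation) with 0 of 5 genes past the threshold, over all genes and adjusted over the list alone. Its median change of 0.92 fell to 0.30 without cKO sham replicate 2 and to 0.56 without cKO EDL replicate 3, where it did not pass (adjusted p = 0.135 and 0.133). Hba-a1 changed by 0.97 ± 0.36. The primary cilium and hedgehog pathway lists did not pass in either genotype (adjusted p = 0.929 and 0.249 in Ctl, 0.715 and 0.354 in cKO), and 3 of 17 hedgehog genes rose in cKO, among them the co-receptor gene Gas1 (0.65 ± 0.14).

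Many of the same genes changed after EDL in both genotypes, in arrays that the comparisons do not share. Of the genes past the threshold in both, 461 rose and 712 fell, and 0 went in opposite directions. Independent calls would share 36.7 rises and 47.5 falls. Both comparisons use the same estimate of spread for each gene, however, so their calls are not independent. Of the 2702 genes past the threshold in either genotype, 97.6% had the same sign in both. Across these genes, which are not independent replicates, the Pearson correlation of the changes was 0.938. The first principal axis of the changes had a slope of 1.14 (cKO over Ctl), which is not a regression slope. Over all genes the Pearson correlation was 0.828 and the Spearman correlation 0.587. In Ctl alone 556 genes passed, 523 of them with the same sign in cKO, and in cKO alone 973 passed, 940 with the same sign in Ctl. Whether a gene's change differed between genotypes was tested by the interaction.

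**Figure D4:**
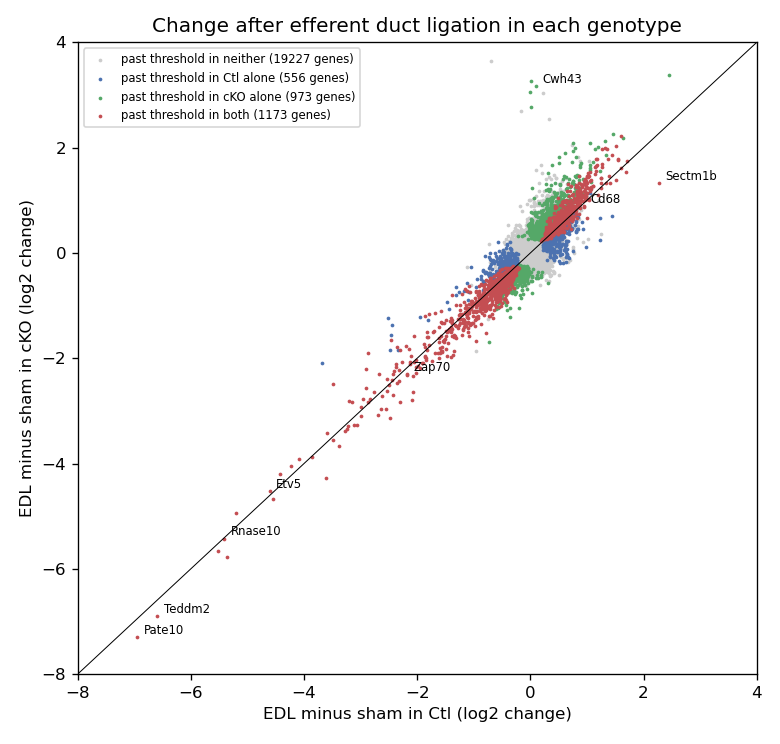
Log2 change after EDL in Ctl (horizontal axis) and in cKO mice (vertical axis), 1 point per gene, coloured by the genotypes in which it passed the threshold, with the line of equal change. The 1173 genes past the threshold in both lie in the quadrants of equal sign.

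The series states its purpose as the comparison of Ctl and cKO within each surgical condition. In sham tissue (n = 3 and 4) 0 genes passed the threshold by limma, with 800 genes at an unadjusted p under 0.05 where 1096 would be expected by chance. After Benjamini-Hochberg adjustment the authors' own p-values also left 0. The smallest p among lower genes belonged to Ly6f, Defb26 and Crabp2, with cKO minus Ctl differences of -1.82 ± 0.35, -2.93 ± 0.59 and -0.55 ± 0.12, and among higher genes to Abca12, Mcm3ap and Abhd16b (0.52 ± 0.10, 0.47 ± 0.09 and 0.48 ± 0.10), all at an adjusted p of 0.999. Without Ctl EDL replicate 4, an array of another group that widens the shared estimate of spread, 4 genes passed as lower in cKO sham tissue: Defb22 (-3.77), Defb38 (-3.12) and Pate3 (-3.36) at an adjusted p of 0.00964, and Pate1 (-3.06) at 0.0236. Defb22 and Pate1 were chosen after their values were seen. The macrophage, fibroblast and matrix, endothelial, erythroid and adipocyte lists were lower in cKO sham tissue by camera (medians -0.30, -0.30, -0.25, -0.74 and -0.34; adjusted p = 0.000685, 0.00109, 0.000133, 2.53e-05 and 0.00409). With an estimated correlation their adjusted p was 0.666, 0.834, 0.666, 0.666 and 0.666, none of their genes passed over all genes or adjusted over the list alone, and 0 of these lists passed without cKO sham replicate 2. Their medians were then -0.05, 0.09, -0.05, -0.19 and -0.36, so that the adipocyte difference stayed as large. Without Ctl sham replicate 3 the macrophage, fibroblast and adipocyte lists did not pass (medians -0.18, -0.12 and -0.24; adjusted p = 0.162, 0.266 and 0.32), nor did the adipocyte list without cKO sham replicate 3 or Ctl sham replicate 4 (-0.19 and -0.24, adjusted p = 0.164 and 0.0951). In simulated data 97.0% of 2-fold changes and 71.6% of 1.5-fold changes were recovered in this comparison. Their noise was independent between genes, so these shares do not show that a real change of that size would pass. In the real arrays 17 genes stood at least 2-fold lower in cKO sham tissue at an unadjusted p under 0.05 (limma), and none passed.

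In EDL tissue (n = 3 and 4) 0 genes passed between genotypes by limma, and the authors' p-values left 0 after the same adjustment. At an unadjusted p under 0.05 there were 1333 genes where 1096 would be expected by chance. Of 35 splits of these arrays, 13 gave as many. Fam186b, Nav3 and Pcnt had the smallest p among higher genes (0.59 ± 0.09, 0.54 ± 0.09 and 0.48 ± 0.08; adjusted p = 0.141, 0.179 and 0.179). Lrrc10b and Sec14l4 were among the 3 lower genes with the smallest p (-0.57 ± 0.10 and -0.50 ± 0.10; adjusted p = 0.222 and 0.382). The multiciliated cell list was lower in cKO EDL tissue (median -0.30; adjusted p = 9.88e-05, and 0.298 with an estimated correlation), with 0 of 16 genes past the threshold and 3 lower adjusted over the list alone, among them the cilium genes Rsph4a (-1.08 ± 0.30) and Ccdc39 (-0.32 ± 0.09). The clear cell and T and NK cell lists were also lower (medians -0.10 and -0.08; adjusted p = 0.039 and 0.0268, and 0.677 and 0.518 with an estimated correlation). Adjusted over the list alone 1 and 0 of their genes passed, with Atp6v0a4, a proton pump subunit of clear cells, at -0.31 ± 0.08. The smooth muscle, proliferation, basal cell, sperm and cholesterol synthesis lists were higher in cKO EDL tissue (medians 0.51, 0.37, 0.12, 0.21 and 0.09; adjusted p = 3.76e-06, 1.41e-05, 0.039, 0.0154 and 0.0268). With an estimated correlation their adjusted p was 0.542, 0.82, 0.542, 0.771 and 0.822, and none of their genes passed over all genes or adjusted over the list alone. Of these 8 lists, the multiciliated cell and smooth muscle lists passed without each array, at -0.20 without Ctl EDL replicate 5 and 0.32 without cKO EDL replicate 4. Without cKO EDL replicate 2 the proliferation, basal cell, sperm, cholesterol synthesis, clear cell and T and NK cell lists did not pass (adjusted p = 0.137, 0.0725, 0.101, 0.477, 0.0642 and 0.0725). The last 5 did not pass without cKO EDL replicate 4 (adjusted p = 0.208, 0.337, 0.115, 0.133 and 0.133) or Ctl EDL replicate 3 (adjusted p = 0.151, 0.0749, 0.255, 0.154 and 0.149) either. The clear cell list also did not pass without Ctl EDL replicate 2 or 5 or cKO EDL replicate 3 (adjusted p = 0.0583, 0.113 and 0.104), the T and NK cell list without Ctl EDL replicate 2 (0.0906), the basal cell list without Ctl EDL replicate 4 (0.203), and the sperm and cholesterol synthesis lists without Ctl EDL replicate 5 (0.115 and 0.131). Where the calls were lost the medians were 0.15 for proliferation, 0.11 to 0.15 for basal cell, 0.15 to 0.22 for sperm, 0.01 to 0.09 for cholesterol synthesis, -0.16 to -0.07 for clear cell and -0.09 to -0.07 for T and NK cell genes. Some medians grew instead. Without cKO EDL replicate 3, proliferation, cholesterol synthesis and T and NK cell genes stood at 0.74, 0.14 and -0.15. Without Ctl EDL replicate 4, cholesterol synthesis and T and NK cell genes stood at 0.13 and -0.16. Mylk and Pcna differed by 0.34 ± 0.11 and 0.37 ± 0.16. With the values of the second table the basal cell, clear cell and T and NK cell lists did not pass by camera (adjusted p = 0.12, 0.052 and 0.0505).

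The interaction, the EDL change in cKO minus that in Ctl, tested whether the response to EDL differed between genotypes. By limma 0 genes passed, with 899 at an unadjusted p under 0.05 where 1096 would be expected by chance. With simulated noise independent between genes, between 83.6% and 88.1% of 2-fold differences but only 28.4% to 35.8% of 1.5-fold differences were recovered. Slurp1, Sipa1l2 and Nudt16l2 had the smallest p among genes with a higher change in cKO (0.57 ± 0.11, 0.59 ± 0.12 and 0.71 ± 0.15; adjusted p = 0.958, 0.985 and 0.985), and Lrrc10b, Abca12 and Klrb1c among those with a lower change (-0.89 ± 0.14, -0.79 ± 0.14 and -0.86 ± 0.17; adjusted p = 0.427, 0.518 and 0.958). Krt5 and Krt14 had interactions of 0.46 ± 0.14 and 0.64 ± 0.26 that did not pass (adjusted p = 0.985 each). By camera 8 lists had a higher change in cKO: basal cell, sperm, macrophage, proliferation, fibroblast, smooth muscle, endothelial and erythroid (adjusted p = 0.0142, 0.0144, 0.0226, 2.21e-06, 0.000157, 4.41e-06, 0.00104 and 0.00104). The multiciliated cell list had a lower one (adjusted p = 0.0106). With an estimated correlation 0 of these 9 lists passed (adjusted p from 0.496 to 0.671), and none of their genes passed over all genes or adjusted over the list alone. Of the 9, the smooth muscle and proliferation lists passed without each array, with medians as low as 0.37 without cKO sham replicate 2 and 0.30 without Ctl sham replicate 3, against 0.68 and 0.59 with all arrays. Without cKO sham replicate 2 the macrophage, fibroblast, endothelial and erythroid lists did not pass (adjusted p = 0.584, 0.258, 0.243 and 0.0705). Over all arrays left out in turn, the macrophage list lost its call without 8 of 14 arrays (adjusted p up to 0.584), the sperm list without 7 (up to 0.196), the basal cell list without 4 (up to 0.077) and the multiciliated cell list without 2 (up to 0.0705). The endothelial receptor gene Kdr had an interaction of 0.77 ± 0.25. With mouse as a fixed replicate block in the list test the interferon-stimulated and adipocyte lists also passed (adjusted p = 0.0271 each), but they did not with an estimated correlation in the model without the block (0.725 and 0.671).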

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

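In this part, the tests of whether 1 array carries the lower lists of cKO sham tissue were chosen after the result was seen, as were the list tests with an array left out; the other splits of the arrays and the test of the share of non-epithelial tissue were set before. Within the Ctl groups of 4 arrays, 11 of 266 sets of values held an array far from the other 3 by Dixon's ratio (gap over range above its 95% critical value), where chance alone gives about 1 in 20. Among Ctl sham arrays Trp63 read 10.33 in replicate 3 against 10.65 to 10.70 in the others (ratio 0.850), and Slurp1 read 6.40 in replicate 3 against 6.13 to 6.16 (ratio 0.881). Cd74 read 10.63 in replicate 4 against 10.38 to 10.41 (ratio 0.871), and the antimicrobial peptide gene Defb26 read 9.72 in replicate 4 against 8.88 to 8.94 (ratio 0.929). H2-DMb2 read 9.32 in replicate 2 against 9.39 to 9.40 (ratio 0.837), and the chemokine gene Ccl9 read 5.96 in replicate 5 against 8.23 to 8.58 (ratio 0.866). The proliferation list stood at 0.61 in Ctl sham replicate 3 against -0.53 to -0.40 in the others (ratio 0.882), and the epithelial junction list at 0.05 against -0.02 to -0.01 (ratio 0.869), as medians relative to the mean of all arrays. Among Ctl EDL arrays Lgals1 read 10.21 in replicate 2 against 11.14 to 11.19 (ratio 0.945), Sec14l4 7.90 in replicate 5 against 7.67 (ratio 0.983), and Atp6v0a4 7.94 in replicate 3 against 7.78 to 7.80 (ratio 0.926).

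The change after EDL differed between genotypes for 9 gene lists by camera. With an estimated correlation 0 of them passed (adjusted p from 0.496 to 0.671). The median interactions on the log2 scale were 0.837 for erythroid, 0.678 for smooth muscle, 0.586 for proliferation and 0.570 for fibroblast genes, followed by sperm (0.312), endothelial (0.278), macrophage (0.225) and basal cell genes (0.108); multiciliated cell genes had -0.228. With an array left out these medians moved by over 1.5 times. Without cKO sham replicate 2 the smooth muscle and erythroid lists stood at 0.37 and 0.26, without Ctl sham replicate 3 the proliferation and smooth muscle lists at 0.30 and 0.44, without Ctl sham replicate 2 the sperm and basal cell lists at 0.17 and 0.05, and without cKO EDL replicate 2 the proliferation and multiciliated cell lists at 0.35 and -0.10. Without cKO EDL replicate 3 the proliferation and erythroid lists stood at 0.90 and 0.47, without cKO sham replicate 3 the fibroblast and macrophage lists at 0.86 and 0.38, and without Ctl sham replicate 3 or 5 the macrophage list at 0.14 and 0.36. The basal cell list stood at 0.17 without Ctl EDL replicate 2, and the multiciliated cell list at -0.15 without Ctl EDL replicate 5 and -0.14 without cKO sham replicate 4. Of 35 ways to split the 7 mice by genotype, 8 gave as many lists, with 9 for the real split and up to 14 for another, so chance cannot be excluded. For single genes the real count was 0, which any split reaches (35 of 35), so that this count says nothing on chance, and another split gave 19 genes. At an unadjusted p under 0.05, 13 of 35 gave as many as the real 899, and another 1866.

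The fibroblast, endothelial, macrophage, erythroid and adipocyte lists were lower in cKO than in Ctl sham tissue by camera, and the same sham arrays enter the interaction. None of their genes passed, over all genes or adjusted over the list alone, and with an estimated correlation the lists' adjusted p was 0.666 to 0.834. Without cKO sham replicate 2 the fibroblast, endothelial, macrophage and erythroid lists did not pass and stood at 0.09, -0.05, -0.05 and -0.186, against -0.30, -0.25, -0.30 and -0.74 with all arrays. The interactions of the macrophage, fibroblast, endothelial and erythroid lists fell to 0.08, 0.10, 0.09 and 0.26 without passing, so this array may carry much of the pattern in these 4 lists. As the only source it would need to stand at -0.897, -0.894, -0.759 and -2.22 relative to the other cKO sham arrays. It stood at -0.468, -0.906, -0.476 and -1.757. For macrophage and endothelial genes this fell short by more than the SD between arrays (0.261 and 0.191). Without Ctl sham replicate 3 the macrophage and fibroblast lists did not pass either (camera adjusted p = 0.162 and 0.266). For the adipocyte list, cKO sham replicate 2 as the source was argued against, since the list stood at -0.361 without the array and -0.339 with all arrays, though its call was lost (adjusted p = 0.0814). A lower share of non-epithelial tissue in it was left open: fibroblast, smooth muscle, endothelial, macrophage and erythroid genes stood at -0.91, -0.64, -0.48, -0.47 and -1.76 relative to the other cKO sham arrays, but adipocyte genes at 0.127. That value passed the bound of 0.1 set beforehand to exclude this explanation, by less than the spread of the adipocyte list between arrays (SD 0.284), a criterion applied once the value was seen. Of 35 splits of the sham arrays, 27 gave at least the real 5 lists, with up to 14 for another, so chance cannot be excluded. An effect of the genotype stays open, untested.

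One signal lay outside the data used for the comparisons. Of 6640 lines of the second table that the log2 table lacks, 1 passed the threshold, with a log2 change after EDL in cKO of 2.31 (limma adjusted p = 0.0395).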

How the results depend on the processing

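The second table as a whole and the list tests with an array left out were chosen after the data were seen. Rnase10, Etv5, Lcn9 and Cd68 and the initial segment and ERK lists kept their direction and call after EDL in both genotypes under every alternative run on them. Krt5 lost its call in Ctl without both arrays of replicate 2 (0.40, adjusted p = 0.0627) or 5 (0.39, adjusted p = 0.0931). After EDL, 1552 to 2506 genes passed in Ctl under 12 alternatives and 1955 to 3044 in cKO under 11, including mouse as a replicate block (1629 and 1955 fixed, 2090 and 2607 random). With only the arrays compared, which leaves fewer arrays to estimate the spread, 1375 passed in cKO. A change of at least 1.5-fold was met by 783 genes in Ctl and 1169 in cKO, and an unadjusted p under 0.05 with at least 2-fold by 304, 520, 17, 15 and 12 in the order Ctl EDL, cKO EDL, genotype in sham, genotype in EDL and interaction. The counts of 0 for genotype and interaction stayed 0 under the other alternatives with all arrays. The Arl13b difference was 0.10 to 0.22 in sham and -0.20 to -0.07 in EDL tissue under 10 alternatives, and 0.02 to 0.22 and -0.28 to -0.06 with an array left out. With arrays or mice left out, 788 to 1772 genes passed for EDL in Ctl, 712 to 2197 in cKO, 0 to 4 for genotype in sham tissue, 0 for genotype in EDL tissue and 0 for the interaction. The count fell to 788 without both arrays of Ctl replicate 5, 1071 without those of Ctl replicate 4, 712 without those of cKO replicate 2 and 1075 without those of cKO replicate 4, and to 1063 and 1305 without the sham or the EDL array of cKO replicate 2; the 4 genes came without Ctl EDL replicate 4. Of the genes past the threshold that the naming rule covers, 62 of 84 in Ctl and 62 of 104 in cKO kept it when any 1 array was left out. Without cKO sham replicate 2, 37 of the 104 lost it, and without cKO EDL replicate 2, 30 did. In Ctl 15 of the 84 lost it without any of Ctl EDL replicates 3, 4 and 5 or Ctl sham replicate 5, among them Timp1 at an adjusted p of 0.11 without the last. With trended and robust variances 19 of these genes lost their call, with only the arrays compared 33, with mouse as a fixed replicate block 17, with mouse as a random block 0 and with median centring 11. For gene lists, an estimated correlation left 2, 2, 0, 0 and 0 in the same order, and fry gave 16, 15, 0, 0 and 0. The lists by fry were not all those by camera. In Ctl the cytokine, interferon-stimulated, proliferation, fibroblast and endothelial lists did not pass (fry adjusted p from 0.0673 to 0.416). In cKO the cytokine, interferon-stimulated, proliferation, smooth muscle and erythroid lists did not (0.0626 to 0.116). By fry alone the basal cell, beta-defensin, clear cell, apoptosis, injury and repair, and immediate early lists passed in Ctl (0.000726 to 0.0386). With an array left out 13 to 17 lists passed for EDL in Ctl, 15 to 18 in cKO, 0 to 11 for genotype in sham tissue, 3 to 9 in EDL tissue and 6 to 14 for the interaction. For genotype in sham tissue 0 passed without cKO sham replicate 2, 2 without Ctl sham replicate 3, 8 without cKO sham replicate 4, 9 without Ctl sham replicate 2 or cKO sham replicate 3, and 11 without Ctl sham replicate 5. In EDL tissue 3 passed without cKO EDL replicate 2 or 4 and 4 without Ctl EDL replicate 3, and for the interaction 14 without cKO EDL replicate 3 or Ctl sham replicate 5. The fibroblast list in sham tissue ranged from -0.50 to 0.09 and reversed, to 0.093 (adjusted p = 0.51), without cKO sham replicate 2. Where a count moved with 1 array, the cause was not tested. Genes whose mean lay near the receptor background have compressed changes, which limits the folds given for them.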

Other observations

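In this part the tests of tissue of one stretch, of an Arl13b effect alike in both surgeries, of the authors' normalization and of the share of epithelium, with its other pairings, were chosen after the results were seen; the other splits of the arrays were set before. Some genes went apart from the lists they belong to. Actg2, a smooth muscle actin, fell after EDL (-3.48 ± 0.36 in Ctl and -2.48 ± 0.42 in cKO) while 4 other smooth muscle genes rose in cKO. Zap70, a kinase known from T cells, fell (-2.18 ± 0.21 and -2.3 ± 0.24) while the T and NK cell list did not pass, and Klrb1c fell in cKO (-1.21 ± 0.13) and did not pass in Ctl (-0.36 ± 0.11), where it passed without Ctl EDL replicate 2 or cKO EDL replicate 2 or 3 (adjusted p = 0.047, 0.0492 and 0.0336). Tgfb1 fell (-0.57 and -0.49) among cytokine genes of which several rose, and H2-DMb2 fell (-0.55 and -0.77) while Cd74 rose by 0.71 and 0.68. In cKO Tgfb1 did not pass without sham replicate 2 or 3 or EDL replicate 3 or 4 (-0.47 to -0.40, adjusted p from 0.0805 to 0.101), nor Cd74 without sham replicate 2 or EDL replicate 3 (0.52 and 0.60, adjusted p = 0.0856 and 0.0565). The beta-defensin gene Defb25 fell (-2.53 ± 0.10 and -2.39 ± 0.12), with the list as a whole not past the threshold in either genotype (adjusted p = 0.875 and 0.318).

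Single genes of the hypoxia, multiciliated cell, epithelial junction and NRF2 lists changed after EDL in either direction, while none of these 4 lists passed in Ctl (adjusted p = 0.715, 0.159, 0.68 and 0.934) or in cKO (0.996, 0.551, 0.949 and 0.558). In Ctl 1 hypoxia gene rose and 2 fell, 3 multiciliated cell genes rose and 1 fell with 13 of 16 above 0, 1 junction gene rose and 2 fell, and 0 NRF2 genes passed. In cKO 0, 0, 1 and 3 rose and 2, 1, 1 and 1 fell. Vegfa, which drives vessel growth, fell (-1.46 ± 0.12 in Ctl and -1.70 ± 0.14 in cKO), as did Egln3, an oxygen sensor (-0.81 ± 0.11 and -0.80 ± 0.13). The ciliogenesis factor gene Foxj1 fell (-0.45 ± 0.09 and -0.51 ± 0.10), and so did the tight junction gene Cldn4 (-0.72 ± 0.09 and -0.57 ± 0.10). Hmox1, a heme-degrading enzyme, rose by 1.83 ± 0.42 in cKO, but did not pass at 1.71 without cKO sham replicate 2 (adjusted p = 0.0591), and stood at 1.21 without cKO EDL replicate 2, where it passed (adjusted p = 0.0304). In Ctl it did not pass (0.81 ± 0.36), and the interaction did not pass either (adjusted p = 0.985).

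A set of 17 genes, 2 of them predicted, stood at least 2-fold lower in cKO than in Ctl sham tissue at an unadjusted p under 0.05 (median -1.82), among them Defb22, Defb26, Defb38, Pate1, Pate3, Cwh43 and Ly6f, several of which are secreted by restricted stretches of the epididymis. The difference was not confined to the log2 table, with a median of -2.96 in sham tissue in the other value table. The normalization of that table is not given, so a processing step that both tables share stays open. A loss alike in both surgeries stays open: their median genotype difference in EDL tissue was -0.18 (quartiles -0.43 and -0.05), but -0.803 without Ctl EDL replicate 4, with 17 of 17 genes lower, and between -0.387 and 0.294 without another EDL array. Tissue of one stretch that entered the arrays in different amounts is a candidate explanation. In Ctl EDL replicate 4, an array of the other genotype, 16 of the 17 lay below the mean of the other Ctl EDL arrays (median -2.48). In 10000 random sets of like intensity the median was -0.19 to 0.21. Those sets were drawn gene by gene, so any genes that vary together could lie outside. The array was also picked after the values were seen. Leaving it out had let Defb22, Defb38, Pate3 and Pate1 of this set pass in sham tissue. A low median of the set in this array was thus likely beforehand, and the random sets are no independent support. Leaving out a Ctl array that is low in these genes also by itself lowers their genotype difference in EDL tissue. Relative to Ctl sham tissue, the medians of Ctl EDL replicates 2, 3, 4 and 5 were 0.57, 1.58, -1.75 and 0.26. So these genes can be low together in a Ctl array too, but the values do not show why. A genotype effect confined to sham tissue stays open and untested.

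The macrophage list rose after EDL in both genotypes by camera, but did not pass with an estimated correlation (adjusted p = 0.0819 in Ctl and 0.0972 in cKO). A lower share of epithelium was taken to raise every other cell type alike, a premise that was not tested. Sham and EDL arrays of one genotype and number were taken as one mouse, which the labels do not state. Per mouse, the macrophage list rose more than the endothelial list by 0.63 on average (SD 0.29), above 0 in 7 of 7 mice. An exact sign-flip test gave a two-sided p of 0.0156, the smallest it can give. The endothelial list was chosen for comparison after the values were seen, so this p-value does not decide on a lower share of epithelium. By the means given below, the fibroblast list rose nearly as much as the macrophage list. The T and NK cell and B cell lists hardly rose at all. The premise of a like rise thus does not hold across these lists, and a lower share of epithelium stays open. In each of the 144 ways to pair the sham and EDL arrays within the genotypes, the macrophage minus endothelial difference lay above 0 in 7 of 7 pairs. Its mean was 0.63 to 0.77 and its SD 0.13 to 0.38. These pairings reuse the same arrays and keep the group difference, so they bear only on the assumed pairing and are no further support. Mean changes per mouse were 1.05 for macrophage, 0.97 for fibroblast, 0.45 for smooth muscle, 0.42 for endothelial, 0.02 for T and NK cell and 0.02 for B cell genes. The macrophage list thus stood apart from the endothelial list but little from the fibroblast list. More macrophages and higher expression within them both stay open and untested.

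Other splits of the arrays bear on the remaining counts. For EDL in Ctl 1 of 35 splits, the real one, gave 1729 genes and no other gave any. That share lies under 0.05 only for arrays taken as independent, which both sides of a mouse may not be, so the splits alone do not exclude chance. Among the 8 splits that part both sides of every mouse, too few for a share under 0.05, the highest other also gave 0. For its lists 3 of 35 gave at least the real 15, with up to 15 in another, so chance cannot be excluded there. The other splits as large kept 3 of the 4 arrays of a surgery together, so that they hold part of the EDL difference. Among the 8 splits that part every mouse the real one gave 15 and the highest other 14. For EDL in cKO the 10 splits are too few for a share under 0.05: the real split gave 2146 genes and 17 lists, and the highest other 2 and 14. For genotype in sham and in EDL tissue the real count of genes was 0, which any split reaches (35 of 35), so that these counts say nothing on chance; the highest other was 1 in sham and 43 in EDL tissue. At an unadjusted p under 0.05, 23 of 35 splits gave as many genes as the real 800 in sham tissue (highest other 1710) and 13 of 35 as many as 1333 in EDL tissue (highest other 2702). In EDL tissue 6 of 35 gave as many as 8 lists (highest other 11). So chance cannot be excluded for these. The split with 43 genes points to a possible structure of the arrays other than genotype, which was not tested.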
